A study of Lotus japonicus with 36 samples.

How the data were processed

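Root nodules of Lotus japonicus MG-20, a model legume whose nodules house nitrogen-fixing rhizobia, were profiled by RNA-seq in 36 libraries that form 12 groups of 3. Per the labels, group T0 was collected before treatment at 4 weeks after inoculation, groups T1 to T6 on days 1 to 6 of supply with 10 mM KNO3, and groups R1 to R5 on days 1 to 5 after nitrate was withdrawn. The series describes the 3 libraries of a group as biological replicates. The nitrate day on which withdrawal began is not given in the sources used here. No untreated group of a later age is among the 12 groups, so days of treatment and plant age run together, and each day is its own harvest.

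Per the submitters' processing notes, reads were trimmed with fastp 0.22.0, aligned with HISAT2 and counted with featureCounts. The genome build, the annotation and the settings for strand and for reads with several matches are not given in the sources used here. RNA was extracted with a TransZol kit and libraries were made with NEBNext Ultra II reagents, per the labels. The authors deposited a table of estimated counts and a table of FPKM values for 50526 rows, of which 50525 carry an Lj transcript model ID and 1 does not. That row, a transcript model under another kind of ID, held 0.00595% of the counts and stayed in the fit. The models belong to 41299 loci, and 34394 models stand alone at their locus. In the deposited estimated counts 49.6% of the values were not whole (tolerance 0.001), so reads were divided over models, and 3753 rows held counts identical to those of another row. A change of a model that shares reads with another model of its locus, with an overlapping model or with a near-identical copy is therefore uncertain as to which model it belongs to. The smallest row total in the table is 51 counts. The deposited FPKM values were used only to derive the length of each model from its count and FPKM, and this length agreed between libraries to within 0.109% for 99% of values above FPKM 20.

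No ID could be paired with a gene name. A RefSeq gene table of assembly LjGifu_v1.2, which is another assembly, matched 0 of the IDs. The gene lists fixed before the data were examined, and the tests planned on them, could therefore not be used, and no gene function is given. By the rule fixed beforehand for this case, the 2 largest rises and the 2 largest falls of each of 3 comparisons (T1 with T0, T6 with T0, R5 with T6) are given by ID. The rule took called models with a mean of at least 10 CPM in the higher group and every library of one group above every library of the other, which happens by chance in 10% of models at 3 against 3.

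Estimated counts were rounded to whole numbers. Differences were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM normalization, filterByExpr) in 1 model fitted to all 36 libraries, so that all groups share 1 estimate of the spread. The filter kept 50475 models. A call needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1, and every adjusted p comes from this test unless another tool is named. Levels are CPM with TMM-adjusted library sizes, given as mean ± SD of 3 libraries. Median differences over a set of models by day were taken from log2 of the group mean CPM plus a pseudocount of 1, which understates changes of models at low level. A fold change against a group with 0 counts in all libraries was computed against a floor of 3 counts per library and is a lower bound, and such bounds and counting intervals (95%) cover counting error only. Single values per library were compared by two-sided exact permutation tests, which at 3 against 3 cannot give a p below 0.1. Principal components were taken from log2 CPM (prior count 2) of the 500 most variable models.

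Library totals ran from 34194054 to 45795038 counts and TMM factors from 0.81 to 1.21. Over the 36 pairs of libraries within groups, a chi-square statistic of the counts, used only to look for a library present more than once, lay between 10.8 and 115.5 per degree of freedom, and no pair was treated as a duplicate. The procedure was tested on simulated data for the comparison of T6 with T0 over 50475 models. In these, 100 models changed 2-fold and 100 changed 4-fold, all of at least 1 CPM. At 2-fold, 54 of 100 changed models passed the adjusted p and 37 were called with the fold threshold. At 4-fold, 86 of 100 were called. Unchanged models gave 3 passes and 1 call. With so few changed models the adjusted p is stricter than in the real comparison, where 29106 models passed it. A true 2-fold change also lies at the fold threshold, which many such models miss by construction. These recoveries therefore do not carry over to the real data.

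Each library was placed on an axis through the mean log2 CPM of T0 (0%) and of T5 (100%) over the 18909 models called between them, so positions of these 2 groups are not independent of the axis. Contrasts that share the T0 libraries were set beside 10 simulations of unchanged groups against shared controls. The control libraries were simulated too, around the T0 means, so deviations of the real T0 libraries are not in them. Correlations are across models with a mean of at least 1 CPM, and models are not independent replicates. The comparisons, their test and the alternatives were fixed before the data were examined: RLE size factors, no low-count filter, the replicate number as a block, DESeq2 1.42.0, a fit of the 2 compared groups alone, no fold threshold, a reversal set taken from T4, and each library left out in turn. Chosen after the data had been seen were the sums of counts per locus, the normalization within 10 bins of model length, the group of the 20 most abundant models, the axis, the day-to-day comparisons, the further comparisons of R1 and R2 with nitrate days and the sets of models with transient or late patterns or beyond both T0 and T6, with the alternatives run on each of these. DESeq2 on the overlap of T6 and R5 was added then too.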

Results

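Gene expression was measured by RNA-seq in mature root nodules of Lotus japonicus MG-20 over a daily course of nitrate supply and nitrate withdrawal. Untreated nodules (T0), nodules on days 1 to 6 of 10 mM KNO3 (T1 to T6) and nodules on days 1 to 5 after withdrawal (R1 to R5) were each represented by 3 libraries, 36 in all. Library totals lay between 34194054 and 45795038 counts over 50526 transcript models. The mean correlation of a library with the others of its group was between 0.953 and 0.975 on the log2 CPM scale. The first principal component held 61.9% of the variance of the 500 most variable models, the second 19.5% and the third 6.51%. Transcript models are the unit of every count given here, and models of 1 locus can share reads.

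The first set of comparisons asked how the nodule transcriptome moved away from its untreated state with each day of nitrate. On day 1, 1010 models were higher and 655 lower than in T0. The count grew to 5326 higher and 4312 lower on day 2, 6621 and 5441 on day 3, and 9309 and 7912 on day 4. On day 5, 10678 models were higher and 8231 lower, and on day 6, 10279 were higher and 9777 lower. Which direction held more calls on day 6 was not stable: RLE size factors gave 9945 higher and 10130 lower, DESeq2 gave 10061 and 10223, and without any 1 of the 6 libraries 9002 to 9581 were higher and 9897 to 10614 lower. The day 6 calls made up 39.7% of the 50475 models tested, in 17042 loci. Among them 5818 models were at least 4-fold higher and 5007 at least 4-fold lower. Calls had an adjusted p under 0.05 by edgeR's quasi-likelihood test and a change of at least 2-fold. With no fold threshold, 4184 models passed on day 1 and 18333 on day 2. The median log2 fold change of all tested models was 0.13 on day 5 and 0.03 on day 6, so directions are relative to a centre close to 0.

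**Figure D1:**
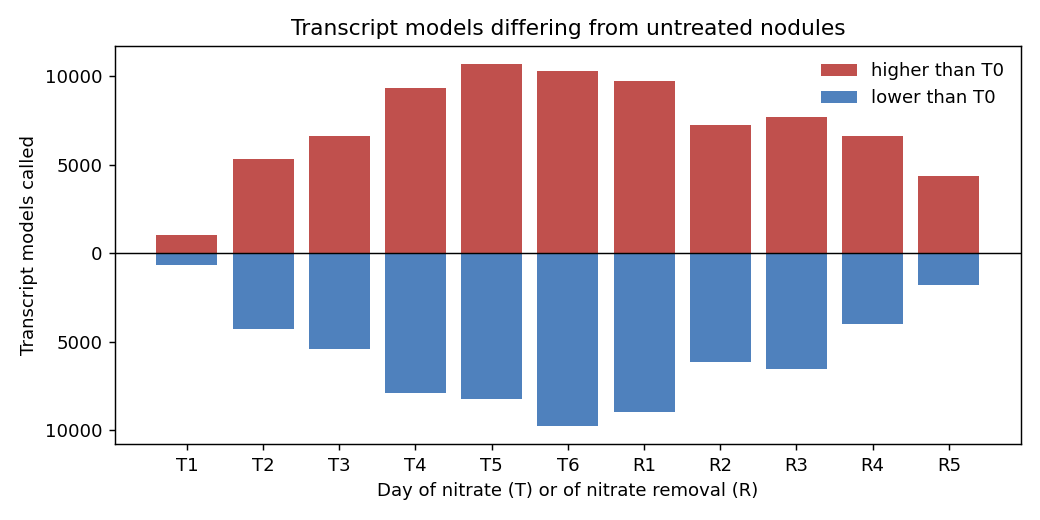
Number of transcript models called higher (red, upward) or lower (blue, downward) than in untreated nodules (T0) on each day of nitrate (T1 to T6) or of withdrawal (R1 to R5), with 3 libraries per group. The bars grow from 1010 higher and 655 lower at T1 to 10279 and 9777 at T6, and shrink to 4333 and 1799 at R5.

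Most models that differed on day 6 had reached their call after the first day. Of the 10279 models higher on day 6, 799 were already higher on day 1 (7.77%), 4123 on day 2 (40.1%), 5645 on day 3 (54.9%), 7132 on day 4 (69.4%) and 8462 on day 5 (82.3%). Of the 9777 models lower on day 6, 445 were lower on day 1 (4.55%), 3282 on day 2 (33.6%), 4613 on day 3 (47.2%), 6236 on day 4 (63.8%) and 7153 on day 5 (73.2%). The largest group of risers began an unbroken run of calls on day 2 (2687 models), whereas among the fallers 2288 began on day 2 and 2624 were called on day 6 without a call on day 5. These onset days depend on the power of each test and are not measured times of induction.

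The comparison of T1 with T0 describes the first day of nitrate. The median called riser was higher by 1.5 on the log2 scale and the median called faller changed by -1.41. The largest rises by the fixed rule were Lj4g3v2951220.2 and Lj4g3v2951220.1, 2 models of 1 locus with nearly equal counts. Lj4g3v2951220.2 rose from 9.01 ± 1.00 CPM in T0 to 96.2 ± 26.7 CPM in T1 (SD, n = 3), a log2 fold change of 3.42 ± 0.68 (SE, edgeR adjusted p = 0.00171), and stood at 327 ± 127 CPM in T6. The largest falls were those of Lj0g3v0059599.1 and Lj1g3v3892190.1. Lj0g3v0059599.1 went from 15.1 ± 2.05 to 0.612 ± 0.0885 CPM, a log2 fold change of -4.61 ± 0.66 (SE, edgeR adjusted p = 8.58e-05), and was at 0.0305 ± 0.0317 CPM in T6. Lj1g3v3892190.1 went from 208 ± 21 to 10.6 ± 0.728 CPM (log2 fold change -4.30 ± 0.54, edgeR adjusted p = 8.17e-06). Its mean level was then higher on each later nitrate day, at 46.8 ± 33.7 CPM on day 2, 134 ± 28.1 CPM on day 4 and 195 ± 92.2 CPM on day 6. On day 2 it was at 85.6 CPM in T2 replicate 2 beside 25.5 CPM in replicate 1 and 29.2 CPM in replicate 3. On day 6 it did not differ detectably from T0 (log2 fold change -0.09 ± 0.47, edgeR adjusted p = 0.879). Of the 1010 models higher on day 1, 799 (79.1%) were also higher on day 6, and of the 655 lower models 445 (67.9%) were also lower. Independent lists of these sizes would share 206 and 127 models, but both comparisons use the same T0 libraries, so part of the excess may come from the shared controls. The day 1 count fell to 1050 without T1 replicate 1.

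By day 6 some models had gone from no counts to abundant or from abundant to no counts. Lj1g3v2326650.1 had 0 counts in the 3 T0 libraries and 206 ± 51.5 CPM in T6, at least 2360-fold higher against a floor of 3 counts per library (edgeR adjusted p = 3.31e-09). Its level was 0.709 CPM on day 2, 22.2 CPM on day 3 and 138 CPM on day 5. The day 2 mean rests on T2 replicate 3, at 2.09 CPM beside 0.0421 CPM in replicate 1 and 0 CPM in replicate 2. Lj1g3v1648770.1 also had 0 counts in T0, reached 4.36 ± 1.57 CPM on day 5 and 97.7 ± 32.8 CPM on day 6, at least 1121-fold above T0 (edgeR adjusted p = 5.12e-05). Among the fallers, Lj6g3v1720560.1 had 69.5 ± 15.2 CPM in T0 and 0 counts in T6, at least 748-fold lower (edgeR adjusted p = 9.04e-09). Lj3g3v2247040.1 had 17.2 ± 1.85 CPM in T0 and 0 counts in T6, at least 185-fold lower (edgeR adjusted p = 7.48e-12).

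The most abundant transcripts of the nodule were exchanged over the same days. Of the 20 models with the highest mean level over all libraries, a group chosen after the data had been seen, 8 were called higher on day 6, 8 lower and 4 neither. The 8 falling models together took 9.67 ± 0.63% of all counts in T0, 3.54 ± 0.48% in T2 and 0.362 ± 0.0896% in T6 (SD, n = 3). The 8 rising models went from 0.463 ± 0.0425% in T0 to 2.06 ± 0.15% in T2 and 5.95 ± 1.58% in T6. The most abundant model, of 1030 bp, was at 0.71, 2.42 and 62.2 CPM in the 3 T0 libraries, so that its T0 mean of 21.8 CPM rests on replicate 3 and is 1.57 CPM without it, and at 31237 ± 11991 CPM in T6. The next, of 471 bp, went from 23827 ± 4979 CPM in T0 to 1240 ± 403 CPM in T6 and was back at 23433 ± 7989 CPM in R5. Over the removal days the falling group stood at 0.941 ± 0.109% in R3, 5.15 ± 1.95% in R4 and 7.42 ± 1.86% in R5, and the rising group at 4.70 ± 1.06%, 1.74 ± 0.35% and 1.68 ± 0.52%. Some of these models share reads with another model of their locus.

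**Figure D2:**
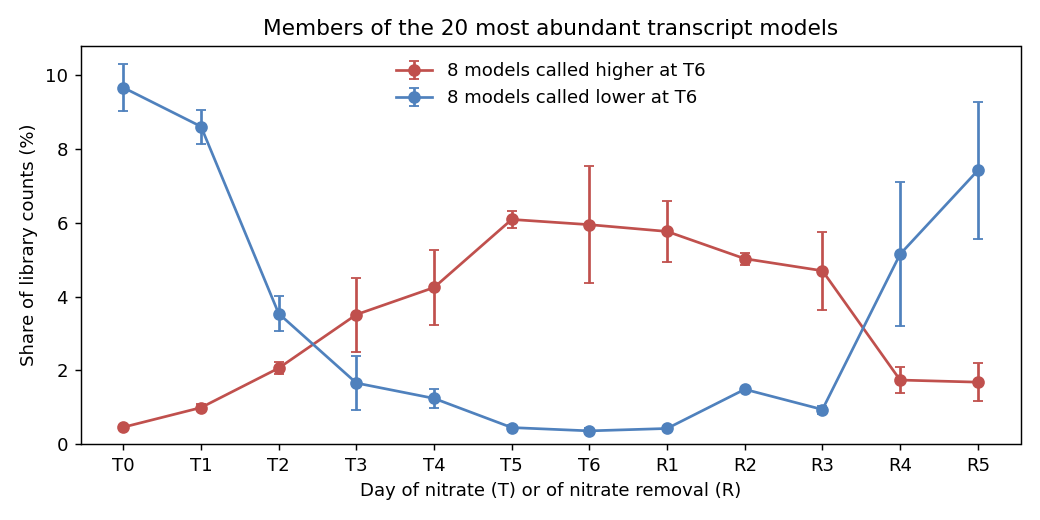
Share of all library counts (%) held by the 8 models called higher at T6 (red) and the 8 called lower at T6 (blue) among the 20 most abundant models, as mean and SD of 3 libraries per group, against the day of nitrate (T) or withdrawal (R). The falling group drops from 9.67% at T0 to 0.362% at T6 and is at 7.42% at R5, while the rising group goes from 0.463% to 5.95% and 1.68%.

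The comparison of R1 with T6 sets the first day after withdrawal beside the last nitrate day. In R1, 73 models were higher and 206 lower than in T6, 279 in all or 0.553% of those tested, while R1 still differed from T0 in 9734 higher and 8973 lower models. Here too the larger direction turned, to 9177 higher and 9559 lower with RLE size factors and to 8477 to 8927 higher and 9166 to 9653 lower without any 1 of the 6 libraries. Lj1g3v2326650.1 was at 200 ± 0.822 CPM in R1 beside 206 ± 51.5 CPM in T6 (log2 fold change -0.04 ± 0.65, edgeR adjusted p = 0.996). For Lj1g3v1648770.1 the R1 level was 18.8 ± 18 CPM beside 97.7 ± 32.8 CPM in T6, a difference that did not pass the test (log2 fold change -2.38 ± 1.14, edgeR adjusted p = 0.441). The count of 279 was unstable. It was 118 without T6 replicate 1, 100 without T6 replicate 2, 76 without R1 replicate 1 and 14 without R1 replicate 2, and it was 596 in a fit of these 6 libraries alone, where 8.39% of the calls were higher in place of 26.2%, and 531 by DESeq2.

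On day 5 after withdrawal, the comparison of R5 with T6 showed 7909 models higher and 6716 lower. Lj6g3v1720560.1, which had 0 counts in T6, was at 33.9 ± 31.2 CPM in R5, at least 364-fold higher (edgeR adjusted p = 1.15e-07), with 69.6, 12.1 and 19.8 CPM in the 3 libraries. Lj1g3v0410090.1 went from 0.139 ± 0.0804 CPM in T6 to 338 ± 163 CPM in R5 (log2 fold change 11.17 ± 0.97, edgeR adjusted p = 3.97e-10), beside 290 ± 66.5 CPM in T0. 1 other model has the same counts as Lj1g3v0410090.1, so the 2 cannot be separated. The largest falls were those of 2 models of 220 bp, Lj0g3v0339409.1 from 10.4 ± 3.19 to 0.0305 ± 0.0528 CPM and Lj0g3v0014139.1 from 12.4 ± 3.14 to 0.0381 ± 0.0660 CPM. Their log2 fold changes were -8.22 ± 0.86 (edgeR adjusted p = 8.65e-09) and -8.18 ± 0.85 (edgeR adjusted p = 1.37e-08). Only 41.7% and 27.8% of their count values were whole, so both share reads with other models and may not be 2 separate falls. Nearly all of their R5 counts lay in replicate 2, and without that library the fitted values were -11.68 and -11.93.

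Models that nitrate had moved tended to move back. This was tested between contrasts that share no library, T5 with T0 on the one side and R5 with T6 on the other. Of the 10678 models higher in T5 than in T0, 9817 (91.9%) had a lower mean in R5 than in T6 and 5366 (50.3%) were called lower. Of the 8231 models lower in T5, 7790 (94.6%) had a higher mean in R5 than in T6 and 5675 (68.9%) were called higher. Among all tested models 13.3% were called lower and 15.7% higher in R5 than in T6. Only 55 of the risers and 26 of the fallers were called further in the same direction. Across 33591 models the log2 fold changes of both contrasts had a Pearson correlation of -0.846 and a Spearman correlation of -0.831, over models that are not independent replicates. Of the falling models, 68.9% were called back and of the rising ones 50.3%, a difference that was not tested as such.

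The return was not complete on day 5 of withdrawal. R5 differed from T0 in 4333 higher and 1799 lower models, so that 70.7% of the differences were models above their untreated level. A fit of the R5 and T0 libraries alone gave 3064 higher and 1570 lower, or 66.1% higher. The main fit shares its estimate of the spread over all groups, although the R4 and R5 libraries scattered more widely on the axis than those of R1 and R2. Calls that involve R4 or R5 may therefore be too many in the main fit. On removal day 1, 84.6% of the models that were higher in T6 were still called higher than T0. This share was 63.0% on day 2, 66.6% on day 3, 55.2% on day 4 and 38.5% on day 5. For the models lower in T6 the shares were 79.9%, 54.4%, 58.5%, 30.1% and 12.8%. The median log2 fold change against T0 of the T6 risers was 2.22 in T6 and 1.00 in R5, and that of the T6 fallers was -2.04 and -0.44. On the log2 scale a model that rose from near 0 can lose most of its gain and still be called above T0. A falling model that regains as much of its loss lies near T0. These values therefore do not show that fallers regained a larger part of their change than risers. Of the T6 risers 33.7%, and of the T6 fallers 64.2%, were called back in R5 against T6 and were no longer called against T0. The T6 and T0 libraries that chose these models were used again here, so part of this movement back may come from chance extremes in them. Lj1g3v2326650.1 was at 4.27 ± 2.81 CPM in R5, at least 49.1-fold above its T0 level of 0 counts (edgeR adjusted p = 0.000191), and Lj3g3v2247040.1 was at 0.969 ± 0.428 CPM, still below T0 (log2 fold change -4.16 ± 0.45, edgeR adjusted p = 1.19e-07). Lj1g3v0410090.1 and Lj6g3v1720560.1 did not differ detectably from T0 in R5 (edgeR adjusted p = 0.83 and 0.25).

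The models higher than T0 in both T6 and R5 numbered 3959, where independent lists would share 882, and the models lower in both numbered 1253, where independent lists would share 348. Unchanged groups yield few calls by construction, so their overlap of 0 in 10 simulations sets no scale for these numbers. Across 33591 models the log2 fold changes of T6 and R5 against T0 had a Pearson correlation of 0.771, beside 0.499 with unchanged groups, and a covariance of 1.62 beside 0.0537, a difference of 1.57. The control libraries were simulated as well, so 0.499 and 0.0537 do not measure what the real T0 libraries contribute. The 3 T0 libraries cannot be split into parts of 2 or more, so part of the excess in overlap may come from the shared controls.

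A position on the axis from T0 (0%) to T5 (100%) summarises each library over the 18909 models called between those groups, whose own means are fixed at the ends. T1 lay at 15.3 ± 4.64%, T2 at 44.5 ± 3.17%, T3 at 63.8 ± 8.29%, T4 at 80.5 ± 2.67% and T6 at 104.7 ± 1.66% (SD, n = 3). After withdrawal R1 lay at 97.6 ± 0.58%, R2 at 71.9 ± 1.09%, R3 at 75.1 ± 3.49%, R4 at 55.5 ± 13.2% and R5 at 38.2 ± 9.73%. The T0 and T5 libraries chose both the models and the direction of the axis, so steps to or from these groups were not tested on it. Among the other steps, T2 from T1, T3 from T2, T4 from T3, R1 from T6, R2 from R1, R4 from R3 and R5 from R4 differed without overlap of libraries (exact permutation p = 0.1, the smallest that 3 against 3 allow), and R3 from R2 differed by 3.21 points (exact p = 0.3). In R4 the libraries ranged from 47.3% to 70.7%, and in R5 from 27.8% to 47.0%, wider than in R1 and R2. A position does not measure how far a library lies off the axis. On the second principal component the T2 libraries lay between 17.5 and 37.2, and the R5 libraries between -64.9 and -27.6. R5 thus lay apart from T2, although their axis positions were near each other.

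**Figure D3:**
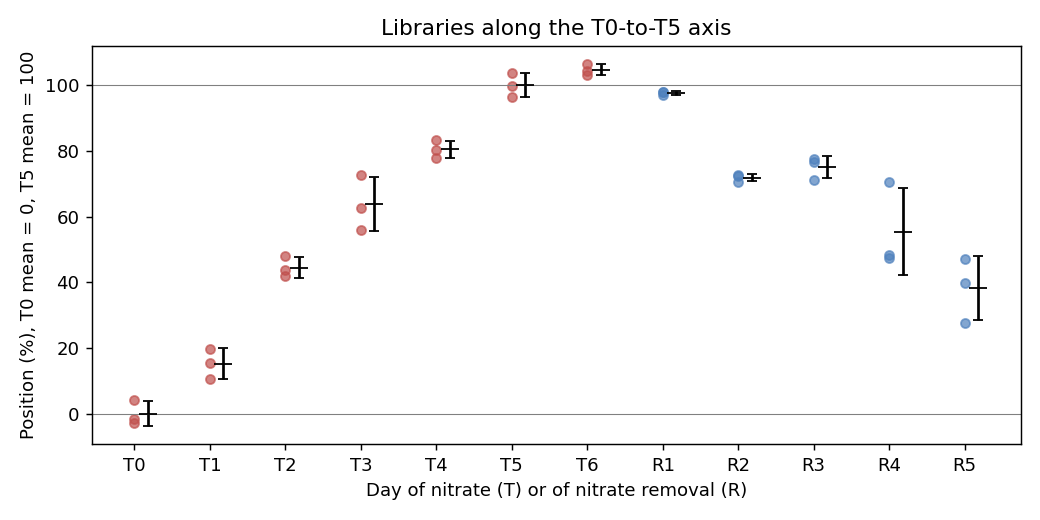
Position of each library (points) on the axis from the T0 mean (0%) to the T5 mean (100%) over 18909 models, with the mean and SD of 3 libraries beside each group; nitrate days (T) are red and withdrawal days (R) blue. Positions go from 15.3% at T1 to 104.7% at T6 and are at 38.2% at R5, with R2 and R3 at 71.9% and 75.1%. Distance from the axis is not shown, so equal positions do not mean equal states.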

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

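The comparison of T6 with T1 and the neighbour statistic for loci 1 place apart were chosen only after the data had been seen, whereas the tests on models beyond both T0 and T6 were set out before their results were known.

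Models that had left the range between untreated and nitrate-treated nodules on day 5 of withdrawal stood out. In R5, 192 models were higher than in both T0 and T6, and 222 were lower than in both, each by calls in the 2 comparisons. Both calls use the same R5 libraries, so a chance extreme in them favours both calls at once. How many of these models arose that way was not tested. The choice of the sets by R5 also enlarges their R5 medians given below. Medians per day are differences from T0 in log2 of the group mean CPM + 1, a scale that understates changes of models at low level, whereas calls rest on fitted fold changes, so that a median here can lie below the fold threshold of the calls. The higher set had a median difference of 0.26 in R2, 0.46 in R3, 0.82 in R4 and 1.02 in R5, and 124 of the 192 were also called higher than T0 in R4. The lower set had median differences of -0.18 in R2, -0.30 in R3, -0.58 in R4 and -0.89 in R5, and 103 of the 222 were also called in R4. On the nitrate days the median of the lower set lay above T0, between 0.02 in T6 and 0.38 in T4. That of the higher set lay between -0.23 in T4 and 0.09 in T5 on those days. Without R5 replicate 2 the lower set grew to 424 models. Normalization within length bins gave 416 models beside 414, which argues against a length-dependent difference between libraries as the source of their number. Only the totals were compared, not whether they were the same models. The lower set was short, with a median length of 832.5 bp beside 1190 bp in the higher set and 1223 bp in all tested models. A single R5 library was argued against as the whole source, since the lowest number with an R5 library left out was 309. The age of the plants may account for the pattern and stays open, because 0 untreated groups harvested after T0 are among the 12 groups, and so does a response to withdrawal itself.

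Loci that stand close together by the number in their ID were called in the same direction at T6 more often than shuffled calls. For loci 1 place apart the ratio of observed to shuffled pairs was 1.95 (highest of 1000 shuffles 1.05), and for loci 5 places apart it was 1.18. Reads shared between adjoining models are a candidate explanation. When pairs whose deviations between replicates correlated above 0.5 were left out, the ratio 5 places apart was 1.004, within the shuffled range, as this explanation predicted. The ratio 10 places apart fell too, from 1.094 to 0.987. The ratio stayed above the highest of the shuffles 1 place apart (1.239 beside 1.065), 2 places apart (1.115 beside 1.055) and, narrowly, 3 places apart (1.062 beside 1.059). Sharing marked by such correlation thus does not carry all of the excess at these 3 distances. Leaving out correlated pairs may also remove neighbours that are truly regulated together, which would lower the ratio in the same way. Models that vary together between replicates wherever they lie would be removed too. Shuffled calls carry no such link, so the ratio can fall at any distance. The fall at 5 places apart therefore does not favour shared reads, and local co-regulation and shared reads cannot be told apart at any of these distances.

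A few models differed in direction between time points. Between days 1 and 6 of nitrate, 14 models were called higher at T1 and lower at T6, and 42 were called lower at T1 and higher at T6, each with a call for T6 against T1. Independent lists of these sizes would share 196 and 133 models, so opposite calls were rare. The shared T0 libraries favour calls in the same direction. Between T6 and R5, 26 models were lower than T0 at T6 and higher than T0 at R5, and 23 were higher at T6 and lower at R5. Beside these, 3959 were higher than T0 at both and 1253 lower at both.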

How the results depend on the processing

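Sums per locus, normalization within length bins and DESeq2 for the 2 overlap results were chosen only after the data had been seen, and the other alternatives for the 17 main results beforehand. Under RLE size factors, no low-count filter, locus sums and length bins, the 17 main results (13 counts of calls, 2 of reversal and 2 of overlap) each stayed within 1.5 times of the reported value. With the replicate number as a block all 17 did too, for example 1508 calls for T1, 19930 for T6 and 5996 for R5 against T0, and 234 for R1 and 14555 for R5 against T6. The replicate numbers did not pair libraries: over 13 comparisons, same-numbered libraries had correlated deviations between -0.157 and 0.186, in 0 comparisons were all correlations over 0.1, and in 0 did every library correlate best with its own number. DESeq2 kept 16 of 17 results within that range and gave 531 calls for R1 against T6 beside 279. Fits of the 2 groups alone kept 12 of 13 and gave 596 for that comparison; the cause was not tested. Without a fold threshold more models passed by construction: against T0 4184 at T1, 18333 at T2, 21102 at T3, 26781 at T4, 28517 at T5, 22293 at R2, 22831 at R3, 18297 at R4 and 11510 at R5, and against T6 419 at R1 and 24029 at R5. T6 and R1 against T0 stayed within 1.5 times. With each library left out in turn, calls ranged from 1050 (without T1 replicate 1) to 1494 for T1 against T0, from 19070 to 20195 for T6 against T0, from 5020 to 6745 for R5 against T0 and from 12701 to 15878 for R5 against T6. For R1 against T6 they ranged from 14 (without R1 replicate 2) to 198, all below the main 279, and were 76 without R1 replicate 1, 100 without T6 replicate 2 and 118 without T6 replicate 1. Of the 120 such values over the 17 results, 115 stayed within 1.5 times. The larger of the 2 directions turned from higher to lower for T6 and R1 against T0, and in 0 of the 8 other settings and 0 of the 6 libraries left out for each of the other 11 counts of calls. For T6 (10279 higher, 9777 lower) it turned with RLE (9945, 10130), DESeq2 (10061, 10223), length bins (9947, 10194) and the 2 groups alone (9044, 9182), and for R1 (9734, 8973) with the same settings (9177, 9559; 9309, 9696; 9159, 9532; 8395, 8784). In both it turned without each of the 6 libraries; the cause was not tested. The named models kept direction and call in 144 of 144 alternatives. They had been chosen from the same data as the largest called changes, so this was favoured in advance. Locus sums were not among their alternatives. Taking the reversal set from T4 in place of T5 kept both results. RLE factors moved the median log2 fold change of all models by at most 0.0762. In the simulation for T6 against T0, 37 of 100 models changed 2-fold were called. Few models changed there and the fold threshold lies at 2-fold, so this does not estimate the recovery in the real data. A model without a call is still not shown to be unchanged. The planned gene list tests were not run, since the IDs could not be paired with names.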

Other observations

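The day-to-day comparisons, the comparisons of R1 and R2 with nitrate days, the transient sets and every test in this part other than the splits of the libraries were chosen only after the data had been seen.

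Some models stood further from T0 on day 2 than on day 6, or on the other side. In T2, 541 models were higher than in both T0 and T6, and 439 were lower than in both. Both calls use the same T2 libraries, so medians furthest from T0 on day 2 are favoured by this choice and are no separate evidence of a peak. Of the 541, 137 were already called higher on day 1 and on day 6 428 were not called against T0, 43 were still called higher and 70 were called lower. Of the 439, 328 were not called on day 6, 32 were still called lower and 79 were called higher. In log2 of the group mean CPM + 1, a scale that understates changes of models at low level and is not the fitted fold change behind the calls, the higher set had a median difference from T0 of 0.42 on day 1, 1.09 on day 2, 0.44 on day 3, 0.55 on day 4 and 0.28 on day 5. The lower set had median differences on this scale of -0.45, -0.97, -0.56, -0.58 and -0.12 on those days. With a library left out the sets ranged from 461 to 581 and from 359 to 476 models.

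The change from one day to the next was uneven. During nitrate supply 3650 models differed between T2 and T1 and 2959 between T5 and T4. After withdrawal 3358 differed between R2 and R1, 556 between R3 and R2 and 4351 between R4 and R3, of which 3176 were higher in R4. For R4 against R3, a fit of those libraries alone gave 2164 calls. The R3 to R2 count was 281 without R2 replicate 1. For R5 against R4 the count was 2120, with 651 higher, but 1044 without R4 replicate 1, and a fit of these 6 libraries alone gave 0 calls by edgeR's quasi-likelihood test with 6529 models at an unadjusted p under 0.05. Other steps moved with single libraries as well. T3 against T2 gave 1902 calls, but 1260 without T2 replicate 3 and 1128 without T3 replicate 3. T6 against T5 gave 2107, but 1271 without T5 replicate 2, 1328 without T5 replicate 3 and 1301 without T6 replicate 1. T4 against T3 gave 1018, and between 417 and 631 without T3 replicate 1 or 2 or any of the 3 T4 libraries.

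By counts of calls, R1 differed least from T6 among the nitrate days. R1 differed from T1 in 15781 models, from T2 in 11456, from T3 in 6860, from T4 in 5157, from T5 in 1855 and from T6 in 279. The count against T5 was 1040 without T5 replicate 2 and 1068 without R1 replicate 2, still above 279. On the axis from T0 to T5, in contrast, R1 lay 2.36 points from T5, a group whose libraries define the axis, so that this distance is not a test, and 7.01 points from T6, without overlap (exact permutation p = 0.1, the smallest possible). Withdrawal may have followed nitrate day 6, which the labels do not state, but the low count of 279 prompted this idea and cannot test it, so it stays open.

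Models abundant late in the nitrate course were seen at trace level in T0 replicate 3. Of 2052 models with at least 100 CPM in T6, 53 were below 0.4% of that level in T0 replicates 1 and 2 and reached a sizable share of it in another nitrate or withdrawal group. Their median level was 0.234% of the T6 level in T0 replicate 3, beside 0.0138% and 0.0287% in T0 replicates 1 and 2, a contrast that this choice of models favours. In 65 models chosen by the mean of the 3 T0 libraries instead, the medians were 0.221%, 0.0326% and 0.0428%, and replicate 3 was the highest of the 3 in 42. Material of a T6 library may have entered this library. Models far higher in T6 than in every other group (17) should then be present in the same proportion, and their counts were 0.627 of those predicted (95% Poisson interval 0.532 to 0.733). These models can be present at a lower level in other groups, and T0 counts of their own were not subtracted. The ratio is therefore not a clean test of T6 material. After this ratio was seen, the set was narrowed to the 11 models near absent from the other T0 libraries, and it became 0.453 (0.368 to 0.551). Both ratios lie below 1 and neither lies below 0.5 by more than its interval, so the question stays open. Material of another late library, or a few nodules further advanced in that sample, would both give levels that follow a later group, and the highest Spearman correlation across these models was 0.900, with R1, beside 0.898 with T6. These sources cannot be told apart, since both predict the same values. Without T0 replicate 3, T6 differed from T0 in 20195 models beside 20056.

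The 6 libraries of each comparison were also split in the other ways into 3 and 3, each split fitted on those 6 libraries alone. There are 10 splits, too few for a share under 0.05. Every other split also mixes the 2 groups, so a real difference widens the spread within both parts and leaves few calls by construction. The counts of the other splits are therefore no measure of calls that arise by chance. For the comparisons with T0, the real split gave 1864 calls for T1, 9207 for T2, 11134 for T3, 15882 for T4, 16597 for T5, 18226 for T6, 17179 for R1, 12442 for R2, 12932 for R3, 9015 for R4 and 4634 for R5, and it gave 596 for R1 and 12736 for R5 against T6. For the day steps it gave 4204 for T2, 1716 for T3, 807 for T4, 2399 for T5, 1223 for T6, 3657 for R2, 633 for R3 and 2164 for R4, each against the day before. The further comparisons gave 16186 for T6 and T1, 12314 for T6 and T2, 5816 for R2 and T6, and 14872, 10995, 6463, 5119 and 1318 for R1 and T1 to T5. In each of these, 1 of the 10 splits, the real one, gave as many calls, and the highest of the other splits gave at most 2. For R5 against R4 all 10 of the 10 splits gave as many as the real 0, and the highest of the others gave 2.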
